A study of Coprinopsis cinerea with 29 samples.

How the data were processed

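Polyadenylated RNA of 29 samples in 9 groups was sequenced, with 3 or 4 samples per group that the series describes as biological replicates. Libraries were made with a TruSeq v2 kit, per the labels' protocols, which does not mark the strand, so reads of overlapping genes on opposite strands were not told apart. Groups were taken from the sample titles. Replicate numbers also come from the titles, and those of H run from 2 to 4. The labels place 3 libraries, replicate 4 of H, P1 and P2, on a flow cell of their own.

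The deposited files hold, for each library, the total read count and the unique read count of 14242 gene models, per the file headers, in the layout of a CLC RNA-Seq export. Reads had been placed on gene models used as their own reference sequences, so the files give no genome position. The version of the mapping software and the assembly behind the gene models are not given in the sources used here, beyond model names that carry AmutBmut1, a strain with mutations in both mating-type factors. The deposited TPM values were read and not tested. Other columns, per the file headers, were the expression value, equal to the total count in every case (0 differed), the length of the gene model in bases, and an RPKM column that held 0 throughout and was not used. Of the lengths, 69.2% were multiples of 3, so the models were not all coding sequence alone. A further deposited table held log2 RPKM for 12003 gene models, made with R 3.0.2, edgeR 3.4.2 and limma 3.18.13 per the submitters' processing notes. Its scaling per library was that of TMM factors computed here to within 0.00241 on the log2 scale.

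Total counts ran from 10736371 to 32199674 reads per library, with a median of 20227323. Between 99.7% and 99.9% of the reads of a library were placed on 1 gene model only, so reads shared between near-identical genes were few. The files do not pair the identifiers with names, and 0 of the 14242 matched a reference table of 13657 genes, made from the assembly of another strain. Tests of gene lists fixed before the data were examined were therefore not run, and positions are not given. Replicate libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 24.9 to 1007 between pairs of a group, so none was counted as a copy of another.

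Total counts were analysed with edgeR 4.0.16 in R 4.3.3. Gene models were kept by the function filterByExpr with the 9 groups, which left 11990 and set aside 2252. The kept models held at least 99.9876% of the reads of each library. Libraries were scaled by TMM, and 1 quasi-likelihood model with a coefficient per group was fitted to all 29 libraries, so that all groups shared an estimate of the spread. The 13 pairwise comparisons were called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. For a difference anywhere among the groups, the adjusted p of the F test had to be under 0.05 and the largest difference between group means at least 4-fold. A gene model was called enriched in a group where it passed against each of the other 8 at 4-fold. These designs were fixed before the data were examined. The test of whether stipe and cap changed alike on maturation was added afterwards. Log2 CPM for correlations and principal components were computed with a prior count of 2.

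Gene models were named by a fixed rule. In each comparison they were the 2 with the largest rise and the 2 with the largest fall among those called, with ranges of CPM that did not overlap between the groups and a mean RPKM of at least 10 in the higher group. Non-overlap alone is met by chance in 10% of unchanged genes with 3 libraries against 3. For a group with 0 reads the ratio was computed against a floor of 3 reads over the group and written as at least that fold. For 1 to 3 reads the ratio was given with an exact Poisson 95% interval. Without a library, these ratios were computed again with the scaling factors kept. The SE given with a log2 change is the size of that change divided by the square root of the F statistic of its test. It was not taken from the fit, and it is approximate where a group has few reads.

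The alternatives were DESeq2 1.42.0, limma 3.58.1 with a trend on the deposited log2 RPKM turned into log2(RPKM + 1) or log2(RPKM + 0.1), relative log expression or library size alone in place of TMM, no filter or a stricter one of at least 10 CPM in 3 libraries, the replicate number as a block, the flow cell as a covariate, the first flow cell alone, only the groups compared, another fold threshold, and leaving out each library. Leaving out YFB_C replicate 3 and YFB_L replicate 1 together was added after the data were seen.

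The tests were run on simulated counts drawn from the means, dispersions and library sizes of the real samples, with no structure among the libraries of a group, with 100 of 11990 genes changed at each of 2 fold sizes. For H against VM, 45% of 2.83-fold and 62% of 4-fold changes were called. For P2 against P1 the shares were 57% and 86%, and for FB_S against YFB_S 40% and 69%. False calls made up 1.83%, 1.38% and 2.68% of all calls. With no gene changed, the test over all groups called 0.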

Results

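Transcript levels were measured by sequencing polyadenylated RNA along the development of Coprinopsis cinerea, the grey shag, a mushroom that fruits readily on agar. The fungus was strain 326, which carries mutations in both mating-type factors and so fruits without a mate. Colonies grew at 37 °C in the dark for 5 days and were then moved to 25 °C under 12 h of light and 12 h of darkness to fruit. The 29 libraries fell into 9 groups that follow fruiting. They were vegetative mycelium (VM, n = 3), which feeds and spreads through the agar, secondary hyphal knots (H, n = 3), the compact hyphal aggregates from which a fruiting body starts, and primordia at stage 1 (P1, n = 4) and stage 2 (P2, n = 4). Young fruiting bodies were dissected into cap (YFB_C, n = 3), lamellae (YFB_L, n = 3), the gills that bear the spores, and stipe (YFB_S, n = 3). Fruiting bodies were divided into cap with lamellae (FB_CL, n = 3) and stipe (FB_S, n = 3). Libraries held between 10736371 and 32199674 counted reads, and 11990 of the 14242 gene models had enough reads to be tested.

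The identifiers are those of the genome project's gene models, and the deposited files pair them with no gene name, product or genome position. Gene models are therefore named below by number, 2 that rose and 2 that fell in each comparison, without a statement of what they encode. Levels are given as CPM, read counts relative to the TMM-scaled library total, with the SD over the libraries of a group, and a call is an edgeR quasi-likelihood adjusted p under 0.05 with a change of at least 2-fold. The labels do not say which cultures the replicates came from, so the p-values measure only the spread between these libraries.

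Libraries were arranged by stage and tissue. The first principal component of log2 CPM held 32.9% of the variance and the second 19.2%. Mycelium, hyphal knots and primordia lay together at one end of the first and the fruiting bodies at the other, and the young fruiting body tissues lay at the high end of the second. Across genes, which are not independent replicates, the median correlation within a group ran from 0.885 in young lamellae to 0.980 in the mature stipe. It was 0.970 between stage 1 and stage 2 primordia, and 0.659 between mycelium and mature cap with lamellae. One library each of young lamellae and young cap stood apart from its group. Lamellae replicates 2 and 3 correlated at 0.991 with each other, while replicate 1 reached at most 0.885 with them. Cap replicates 1 and 2 correlated at 0.988, while replicate 3 reached at most 0.928. Of the 29 libraries, 3 came from a second flow cell, replicate 4 of H, P1 and P2. Replicate 4 of H was closest to replicate 4 of P1 (r = 0.964) and not to a library of its own group, and replicate 4 of P1 was closest to replicate 4 of P2 (r = 0.987). Libraries of the first flow cell came as close. Replicate 4 of H reached 0.962 with P1 replicate 1, and P1 replicate 2 reached 0.992 with P2 replicate 1. The flow cell was thus not told apart from the likeness of these stages.

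**Figure D1:**
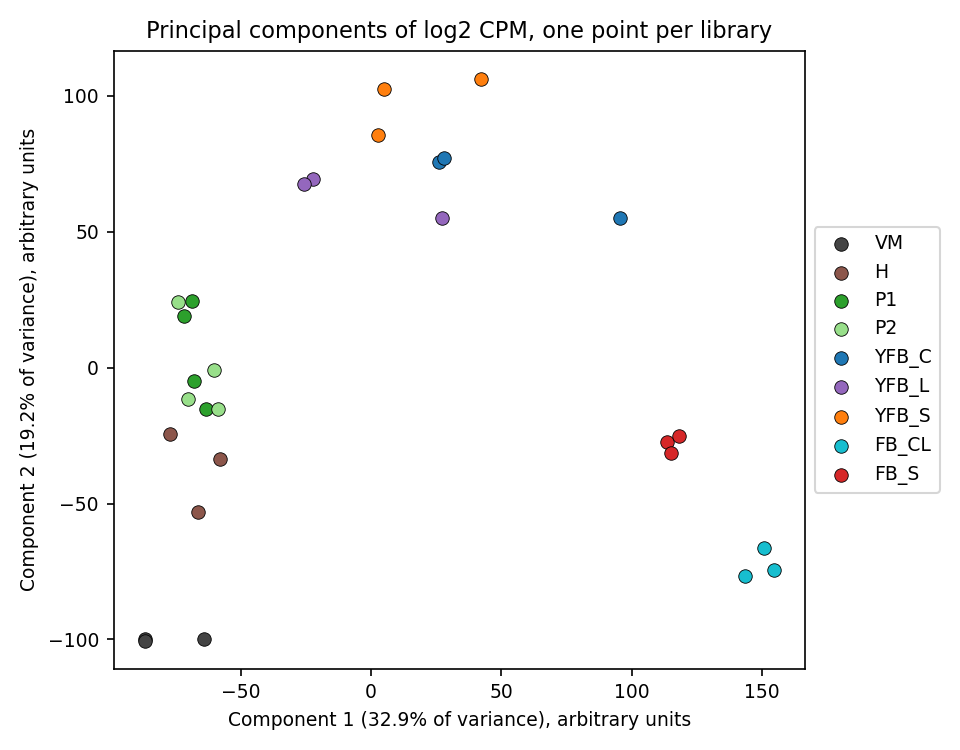
Principal components 1 (32.9% of the variance) and 2 (19.2%) of log2 CPM over 11990 gene models, in arbitrary units, with one point per library coloured by group. The stage 1 and stage 2 primordia overlap, and one library each of YFB_C and YFB_L lies to the right of its group.

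A larger share of the reads came from few genes in the mature than in the young stipe and cap, the mature cap including its lamellae. The 10 most abundant gene models of a library took 4.73% ± 0.605 of the reads in mycelium (SD, n = 3) and 18.3% ± 0.133 in the mature cap with lamellae (SD, n = 3). The share was 13.7% ± 1.87 in the young cap, 5.97% ± 2.64 in young lamellae, 7.64% ± 0.274 in the young stipe and 13.4% ± 1.00 in the mature stipe (SD, n = 3 each). It was 6.37% ± 1.34 in hyphal knots (SD, n = 3), 8.14% ± 1.02 in stage 1 and 6.89% ± 1.32 in stage 2 primordia (SD, n = 4 each). The mean TMM scaling factor moved the other way, from 1.41 ± 0.0644 in mycelium to 0.459 ± 0.0387 in the mature cap with lamellae (SD, n = 3 each). The direction of changes thus rests on this scaling, and beside each comparison whose split into higher and lower genes moved by over 10 percentage points the split under library size alone is given.

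**Figure D2:**
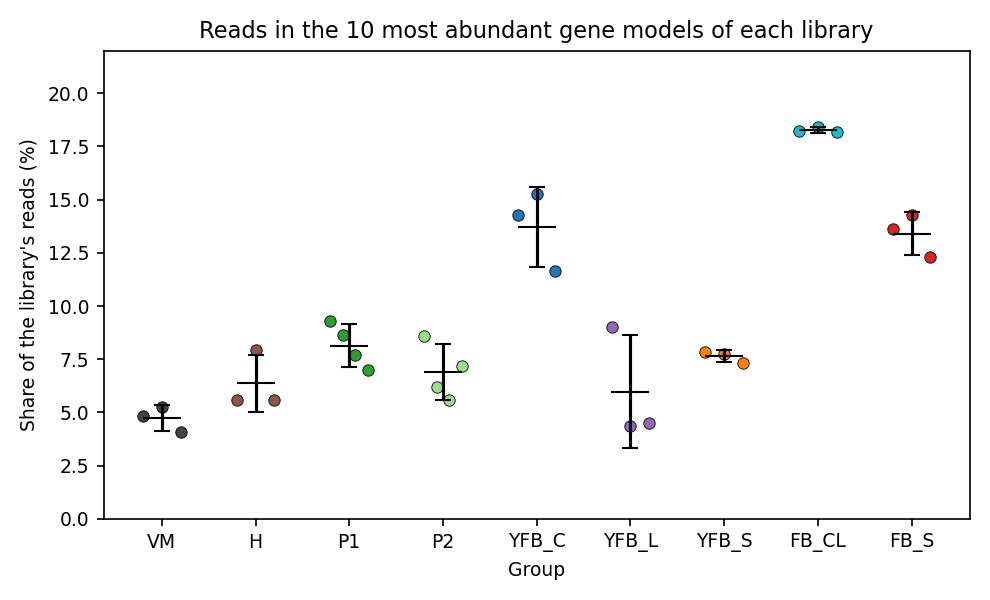
Share of each library's reads (%) on its 10 most abundant gene models, by group. Points are libraries, the horizontal mark is the group mean and the bar its SD; the mature cap with lamellae (FB_CL) has a mean of 18.3% and mycelium (VM) one of 4.73%.

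The onset of fruiting was addressed by secondary hyphal knots against vegetative mycelium. The recorded growth and fruiting conditions are the same for both groups, and do not tell whether mycelium was taken before the move to fruiting conditions. Temperature, light and age of the culture may thus differ along with the stage. In hyphal knots 1314 gene models were higher and 1077 lower, 2391 or 19.9% of those tested, and 1056 changed at least 4-fold. Gene model 477343 rose from 0.438 ± 0.303 CPM in mycelium to 562 ± 339 CPM in knots (SD, n = 3 each), a log2 change of 10.33 ± 0.84 (SE; edgeR adjusted p = 4.00e-09). Gene model 409106 rose from 0.227 ± 0.0471 to 302 ± 318 CPM (log2 change 10.31 ± 1.22 SE; edgeR adjusted p = 1.25e-06). Among the genes that fell, 541489 went from 148 ± 75.7 to 1.04 ± 0.577 CPM (log2 change -7.14 ± 0.78 SE) and 559613 from 84.5 ± 59.3 to 0.656 ± 0.115 CPM (-6.99 ± 0.87 SE), with edgeR adjusted p = 4.31e-07 and 1.40e-05. The log2 change of 477343 was 10.96 without VM replicate 1 and that of 409106 was 8.94 without H replicate 3. Without the libraries of the second flow cell 2232 gene models were called, 1356 higher and 876 lower. The excess of higher genes turned with library size alone, at 1067 higher and 1206 lower (median shift -0.16), and with limma on log2(RPKM + 1), at 1015 and 1021.

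The step from hyphal knot to stage 1 primordium changed far fewer genes, 121 higher and 495 lower of 11990. Gene model 545448 rose from 0.529 ± 0.384 CPM in knots (SD, n = 3) to 32.4 ± 38.8 CPM in stage 1 primordia (SD, n = 4), a log2 change of 5.93 ± 1.27 (SE; edgeR adjusted p = 0.00994). Gene model 500817 rose from 0.277 ± 0.150 to 4.52 ± 2.61 CPM (log2 change 4.00 ± 0.85 SE; edgeR adjusted p = 0.00764). Gene models 380482 and 451332 were lower in primordia, by -4.27 ± 0.66 and -3.91 ± 0.70 on the log2 scale (SE; edgeR adjusted p = 0.00156 and 0.00349). Their means of 189 ± 260 and 121 ± 170 CPM in knots came largely from H replicate 3. Without it the log2 change of 380482 was -1.94 and that of 451332 was -1.45, no longer called (edgeR adjusted p = 0.116), and that of 545448 was 6.66. Without P1 replicate 3 the change of 545448 was 4.76. The count for P1 against H, 616, was unstable. It was 366, 277 and 1008 without H replicates 2, 3 and 4, and 232 and 290 without P1 replicates 2 and 3. A fit to these 7 libraries alone called 1 gene model, 401130, named here after its values were seen (log2 change 2.16, edgeR adjusted p = 0.0290). In that fit the 4 gene models above were not called. The libraries of the first flow cell alone gave 1090, 274 higher and 816 lower, limma 363 on log2(RPKM + 1) and 359 on log2(RPKM + 0.1), and leaving out YFB_C replicate 3 and YFB_L replicate 1 together, chosen after the data were seen, 1022.

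No gene model was called between stage 2 and stage 1 primordia by edgeR, with 212 of 11990 at an unadjusted p under 0.05, where unchanged genes with uniform p would give 599.5, and the smallest adjusted p at 1. limma called 0 on the deposited log2 RPKM, and DESeq2 called 1 gene model, 407867, named here after its values were seen. Its log2 change was 2.89 (DESeq2 adjusted p = 0.0314), and edgeR gave 2.91 with an adjusted p of 1. In simulated counts, which lack any structure among libraries of a group, 4-fold changes were called in 86% of 100 genes and 2.83-fold changes in 57% of 100. These shares need not hold for the real libraries. Among the 9 groups P1 and P2 were also those without any enriched gene, as described below. That follows from the count of 0 between them, since an enriched gene has to pass against every other group, and adds no support. Within the first flow cell the count was also 0.

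Dissected tissues of the young fruiting body showed larger differences from the stage 2 primordium, with 5119 gene models called in the cap, 4138 in the lamellae and 4659 in the stipe. No tissue is named for the primordia, so single tissues are set here against primordia not divided by tissue. Part of each difference can thus lie between tissues and not between stages. In the cap 2637 were higher and 2482 lower. Gene model 501900 rose from 0.739 ± 0.625 (SD, n = 4) to 268 ± 41.5 CPM (SD, n = 3), a log2 change of 8.46 ± 0.70 (SE; edgeR adjusted p = 2.69e-09), and 9.15 without P2 replicate 2. Gene model 448287, the top riser in the cap (1018 ± 1748 CPM, SD, n = 3), owed its level to replicate 3: the log2 change of 9.64 ± 2.05 (SE; edgeR adjusted p = 0.000386) was 2.76 without that library and no longer called (edgeR adjusted p = 0.107). It was 10.59 without P2 replicate 3. Gene model 545448, which had risen at stage 1, was at 78.5 ± 51.1 CPM in stage 2 primordia (SD, n = 4) and had 0 reads in the 3 cap libraries, at least 1155-fold lower (755-fold without YFB_C replicate 1 and 735-fold without replicate 3). Such floors (3 reads over the group) and the intervals given below cover counting error only. Gene model 547131 fell from 7674 ± 3952 (SD, n = 4) to 2.27 ± 1.69 CPM (SD, n = 3), a log2 change of -11.72 ± 1.27 (SE; edgeR adjusted p = 9.63e-08), and -12.52 without YFB_C replicate 3. The first flow cell alone gave 5028. With library size alone as the scaling, 1019 were higher and 5223 lower, and the median gene shifted by -0.89 on the log2 scale. The excess of higher genes also turned without YFB_C replicate 3 (2066 higher and 2122 lower), without it and YFB_L replicate 1 (2180 and 2258), with limma on log2(RPKM + 0.1) (2429 and 2558), in a fit to these 7 libraries alone (2231 and 2569) and at 4-fold (1083 and 1127).

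In young lamellae 2219 gene models were higher and 1919 lower than in stage 2 primordia. Gene model 547131 fell here too, to 0.532 ± 0.250 CPM (SD, n = 3), a log2 change of -13.80 ± 1.36 (SE; edgeR adjusted p = 2.94e-08). Gene model 503005 fell from 809 ± 558 (SD, n = 4) to 0.203 ± 0.318 CPM (SD, n = 3; log2 change -11.92 ± 2.25 SE; edgeR adjusted p = 0.000142). Without YFB_L replicate 1 its change was -15.05, and without replicate 3 it was -11.31. Most of its 17 lamellae reads lay in replicate 1, so the -15.05 rests on very few reads and its size is poorly fixed. The top risers, 448287 with 3219 ± 5545 CPM and 450762 with 366 ± 626 CPM (SD, n = 3), again owed their level to one library. Their log2 changes of 11.31 ± 2.17 and 10.50 ± 1.72 (SE; edgeR adjusted p = 0.000166 and 2.58e-05) were 3.79 and 4.04 without YFB_L replicate 1, still called, and that of 448287 was 12.25 without P2 replicate 3. The first flow cell alone gave 4040, and library size alone 1608 higher and 2407 lower (median shift -0.14). The excess of higher genes also turned without YFB_L replicate 1 (1911 higher and 2230 lower), without it and YFB_C replicate 3 (1975 and 2320), with limma on log2(RPKM + 0.1) (1888 and 2002), in a fit to these 7 libraries alone (1703 and 1832) and at 4-fold (994 and 1082).

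In the young stipe 2130 gene models were higher and 2529 lower than in stage 2 primordia. Gene model 397158 rose from 0.676 ± 0.260 (SD, n = 4) to 618 ± 298 CPM (SD, n = 3), a log2 change of 9.85 ± 1.16 (SE; edgeR adjusted p = 4.75e-07). Gene model 377522 rose from 2.34 ± 0.351 (SD, n = 4) to 958 ± 1406 CPM (SD, n = 3; log2 change 8.68 ± 0.79 SE; edgeR adjusted p = 1.50e-08), and by 5.97 without YFB_S replicate 2. Gene model 481285 was at 9.46 ± 7.93 CPM in primordia (SD, n = 4) with 0 reads in the 3 stipe libraries, at least 216-fold lower. This floor was 131-fold without P2 replicate 1 and 121-fold without YFB_S replicate 1. Gene model 437795 had 2 reads in the stipe against 43.4 ± 40.3 CPM in primordia (SD, n = 4), 1488-fold lower with a 95% counting interval of 412 to 12287. The ratio was 856 without P2 replicate 2 and 834 without YFB_S replicate 1, and without YFB_S replicate 3, which held both reads, it was at least 746. The first flow cell alone gave 4537, and library size alone 1156 higher and 3843 lower (median shift -0.50).

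The 3 tissues of the young fruiting body differed from each other in 3912 to 5229 gene models, against 4138 to 5119 from the primordium. Lamellae and cap differed in 5229 gene models, 2841 higher and 2388 lower in lamellae. Gene model 544085, at 17.5 ± 4.12 CPM in the cap (SD, n = 3), had 0 reads in the lamellae, at least 491-fold lower (307-fold without YFB_L replicate 3). Gene model 496437 fell from 1216 ± 1049 in the cap to 0.20 ± 0.106 CPM in the lamellae (SD, n = 3 each; log2 change -12.52 ± 1.54 SE; edgeR adjusted p = 4.84e-07). Gene models 417135 (540 ± 850 CPM in lamellae, 4.58 ± 4.05 in cap) and 508356 (1909 ± 2761 and 23.0 ± 17.6) were higher in lamellae (SD, n = 3 each). Their log2 changes of 6.87 ± 1.05 and 6.37 ± 1.01 (SE; edgeR adjusted p = 8.68e-06 and 1.36e-05) were 3.43 and 3.77 without YFB_L replicate 1, and 7.90 and 7.20 without YFB_C replicate 3. A fit to these 6 libraries alone called 3479, 1736 higher and 1743 lower, and without YFB_L replicate 1 the split turned to 2734 higher and 2935 lower. Library size alone gave 4616 higher and 1450 lower (median shift 0.72).

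Stipe and cap of the young fruiting body differed in 3912 gene models, 1813 higher and 2099 lower in the stipe. Gene model 546750 stood at 307 ± 203 CPM in the stipe and 0.135 ± 0.126 in the cap (SD, n = 3 each; log2 change 11.08 ± 1.03 SE; edgeR adjusted p = 2.96e-08). Gene model 547131 stood at 1456 ± 1405 and 2.27 ± 1.69 CPM (SD, n = 3 each; log2 change 9.32 ± 1.17 SE; edgeR adjusted p = 1.34e-06). Gene model 547545 had 0 reads in the stipe and 29.0 ± 7.13 CPM in the cap (SD, n = 3), at least 663-fold lower in the stipe (372-fold without YFB_S replicate 1). Gene model 423239 was at 0.496 ± 0.373 in the stipe and 2198 ± 1896 CPM in the cap (SD, n = 3 each; log2 change -12.14 ± 1.34 SE; edgeR adjusted p = 2.47e-07), and at -12.74 without YFB_S replicate 3. The change of 546750 was 10.49, 11.95 and 10.41 without YFB_C replicates 1 and 3 and YFB_S replicate 2. The 11.95 rests on 2 reads in the cap, so its size is poorly fixed. The change of 547131 was 10.12 and 8.23 without YFB_C replicate 3 and YFB_S replicate 3. Scaling by library size alone gave 2976 higher and 1430 lower (median shift 0.44).

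Stipe and lamellae differed in 4985 gene models, 2174 higher and 2811 lower in the stipe. The same pair led the stipe side. Gene model 546750 had 2 reads in lamellae and was 12924-fold higher in the stipe, with a 95% counting interval of 3578 to 106714, and 8087-fold without YFB_L replicate 3 and 8098-fold without YFB_S replicate 2. Gene model 547131 had a log2 change of 11.40 ± 1.27 (SE; edgeR adjusted p = 1.93e-07), and 10.31 without YFB_S replicate 3. On the lamellae side 328275 (650 ± 1124 CPM) and 462778 (540 ± 927 CPM; SD, n = 3 each) stood at 0.187 ± 0.162 and 0.167 ± 0.0701 CPM in the stipe. Their log2 changes of -11.71 ± 2.57 and -11.56 ± 1.88 (SE; edgeR adjusted p = 0.000587 and 2.29e-05) were -1.95 and -4.67 without YFB_L replicate 1, which ended the first call (edgeR adjusted p = 0.323). They were -12.30 and -12.15 without YFB_L replicate 3, and the first was also -12.30 without replicate 2. Library size alone gave 1685 higher and 3298 lower (median shift -0.28). The excess of lower genes turned without YFB_L replicate 1 (2606 higher and 2520 lower), and without it and YFB_C replicate 3 (2678 and 2604).

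Maturation of the cap was followed from the young cap and from the young lamellae to the mature cap with lamellae, which holds both tissues. Against the young cap 5768 gene models were called, 2772 higher and 2996 lower, 2925 of them at least 4-fold. Gene model 463577 rose from 0.174 ± 0.248 to 1515 ± 197 CPM (SD, n = 3 each; log2 change 12.996 ± 0.89 SE; edgeR adjusted p = 4.70e-11) and 468073 from 0.956 ± 0.921 to 4409 ± 626 CPM (12.14 ± 0.94 SE; edgeR adjusted p = 2.74e-10). Without YFB_C replicate 1 these were 15.20 and 13.18. The 15.20 rests on 1 read of 463577 in the cap, so its size is poorly fixed. Gene model 409115, at 41752 ± 7961 CPM in the young cap, fell to 11.1 ± 4.84 CPM (SD, n = 3 each; -11.87 ± 1.24 SE; edgeR adjusted p = 2.68e-08). Gene model 435755 fell from 756 ± 489 to 0.189 ± 0.0789 CPM (SD, n = 3 each; -11.95 ± 1.24 SE; edgeR adjusted p = 2.32e-08). With library size alone 1670 were higher and 4873 lower (median shift -0.78). The excess of lower genes turned with limma on log2(RPKM + 1) (2585 higher and 2484 lower) and log2(RPKM + 0.1) (2882 and 2852), at 4-fold (1481 and 1444), and without YFB_C replicate 3 and YFB_L replicate 1 (3079 and 3052).

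Against young lamellae 6417 gene models were called in the mature cap with lamellae, the most of the 13 comparisons, with 2945 higher and 3472 lower. Gene model 448419 rose from 0.313 ± 0.136 to 10728 ± 2259 CPM (SD, n = 3 each; log2 change 15.03 ± 1.56 SE; edgeR adjusted p = 2.23e-08). In the young cap libraries it already stood at 224, 246 and 679 CPM, so part of this rise can lie between lamellae and cap tissue. Gene model 463577 rose by 12.89 ± 0.87 (SE; edgeR adjusted p = 3.51e-11), and by 13.57 without YFB_L replicate 2. Gene model 391326 fell from 12207 ± 1832 to 6.70 ± 2.25 CPM (SD, n = 3 each; -10.83 ± 1.49 SE; edgeR adjusted p = 1.26e-06). Gene model 382271 fell from 1475 ± 1117 to 1.54 ± 0.514 CPM (SD, n = 3 each; -9.90 ± 1.04 SE; edgeR adjusted p = 2.52e-08), and by -9.14 without YFB_L replicate 1. Scaled by library size alone, 1302 were higher and 6907 lower (median shift -1.47). The excess of lower genes turned without YFB_L replicate 1 (3407 higher and 3314 lower), without it and YFB_C replicate 3 (3447 and 3347), and with limma on log2(RPKM + 1) (2850 and 2839).

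In the stipe 5589 gene models changed from the young to the mature fruiting body, 2768 higher and 2821 lower. Gene models 362776 and 473493 rose from 2.00 ± 1.75 and 3.31 ± 3.51 CPM to 12705 ± 3655 and 12980 ± 3893 CPM (SD, n = 3 each). Their log2 changes were 12.65 ± 2.30 and 11.95 ± 1.19 (SE; edgeR adjusted p = 6.15e-05 and 1.71e-08), and 13.57 and 13.25 without YFB_S replicate 3. Gene model 382271, named above for its fall from young lamellae to mature cap with lamellae, went from 1044 ± 266 to 0.273 ± 0.269 CPM, and 409115 from 17243 ± 3610.2 to 6.89 ± 9.35 CPM (SD, n = 3 each). Their log2 changes of -11.94 ± 1.15 and -11.30 ± 1.22 (SE; edgeR adjusted p = 1.10e-08 and 5.53e-08) were -13.03 and -13.48 without FB_S replicate 2. The -13.03 rests on a part of only 9 reads of 382271 in the mature stipe. Scaled by library size alone, 1671 were higher and 4507 lower (median shift -0.67). The small excess of lower genes turned without FB_S replicate 1 (2662 higher and 2640 lower) or 3 (2676 and 2674), with limma on log2(RPKM + 1) (2455 and 2387) and log2(RPKM + 0.1) (2832 and 2735), and at 4-fold (1435 and 1397).

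The 2 parts of the mature fruiting body differed in 4751 gene models, 2316 higher and 2435 lower in the stipe than in the cap with lamellae. Gene model 457420 stood at 1499 ± 353 CPM in the stipe and 3.08 ± 0.193 in the cap (SD, n = 3 each; log2 change 8.92 ± 1.00 SE; edgeR adjusted p = 1.28e-07). Gene model 468948 stood at 123 ± 32.2 and 0.568 ± 0.591 CPM (7.83 ± 1.17 SE; edgeR adjusted p = 7.04e-06), with a change of 8.92 without FB_CL replicate 1. Higher in the cap were 496007 (3274 ± 919 CPM against 1.15 ± 0.796 in the stipe) and 493901 (886 ± 224 against 0.374 ± 0.333; SD, n = 3 each). Their log2 changes were -11.49 ± 2.38 and -11.21 ± 1.89 (SE; edgeR adjusted p = 0.000326 and 3.12e-05). Without FB_S replicate 2 the first was -12.15, and the second was -10.60 and -11.92 without FB_S replicates 1 and 3. Library size alone gave 3678 higher and 1769 lower (median shift 0.55).

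**Figure D3:**
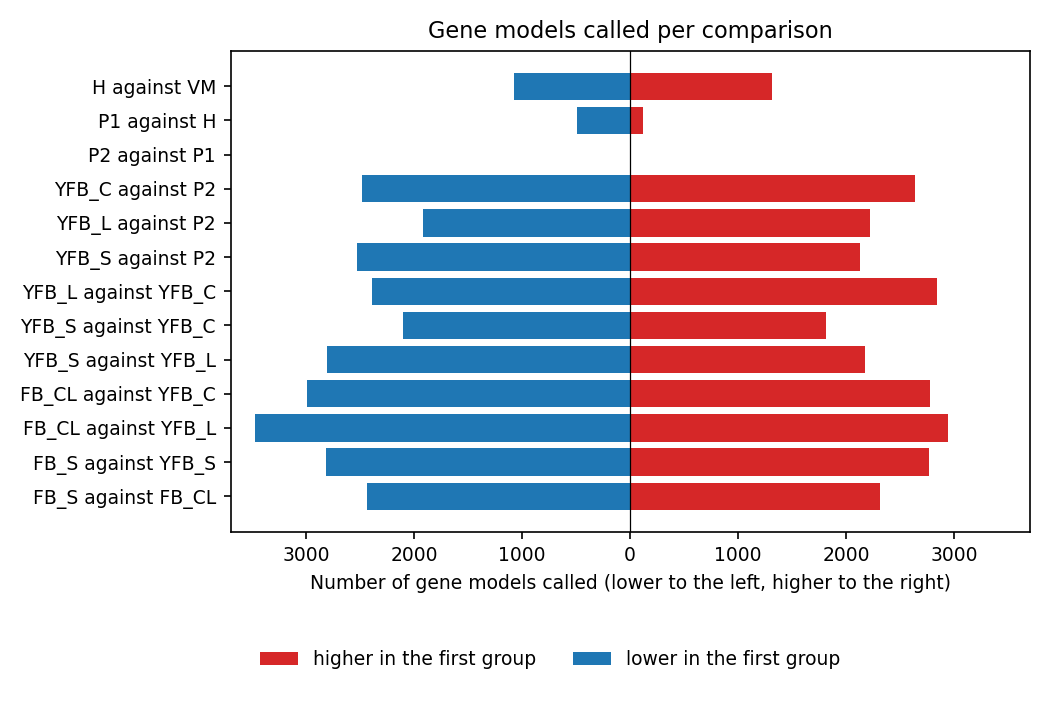
Number of gene models called higher (right, red) and lower (left, blue) in the first-named group of each of the 13 comparisons. The edgeR count is 0 between stage 2 and stage 1 primordia and 6417 between FB_CL and YFB_L.

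**Figure D4:**
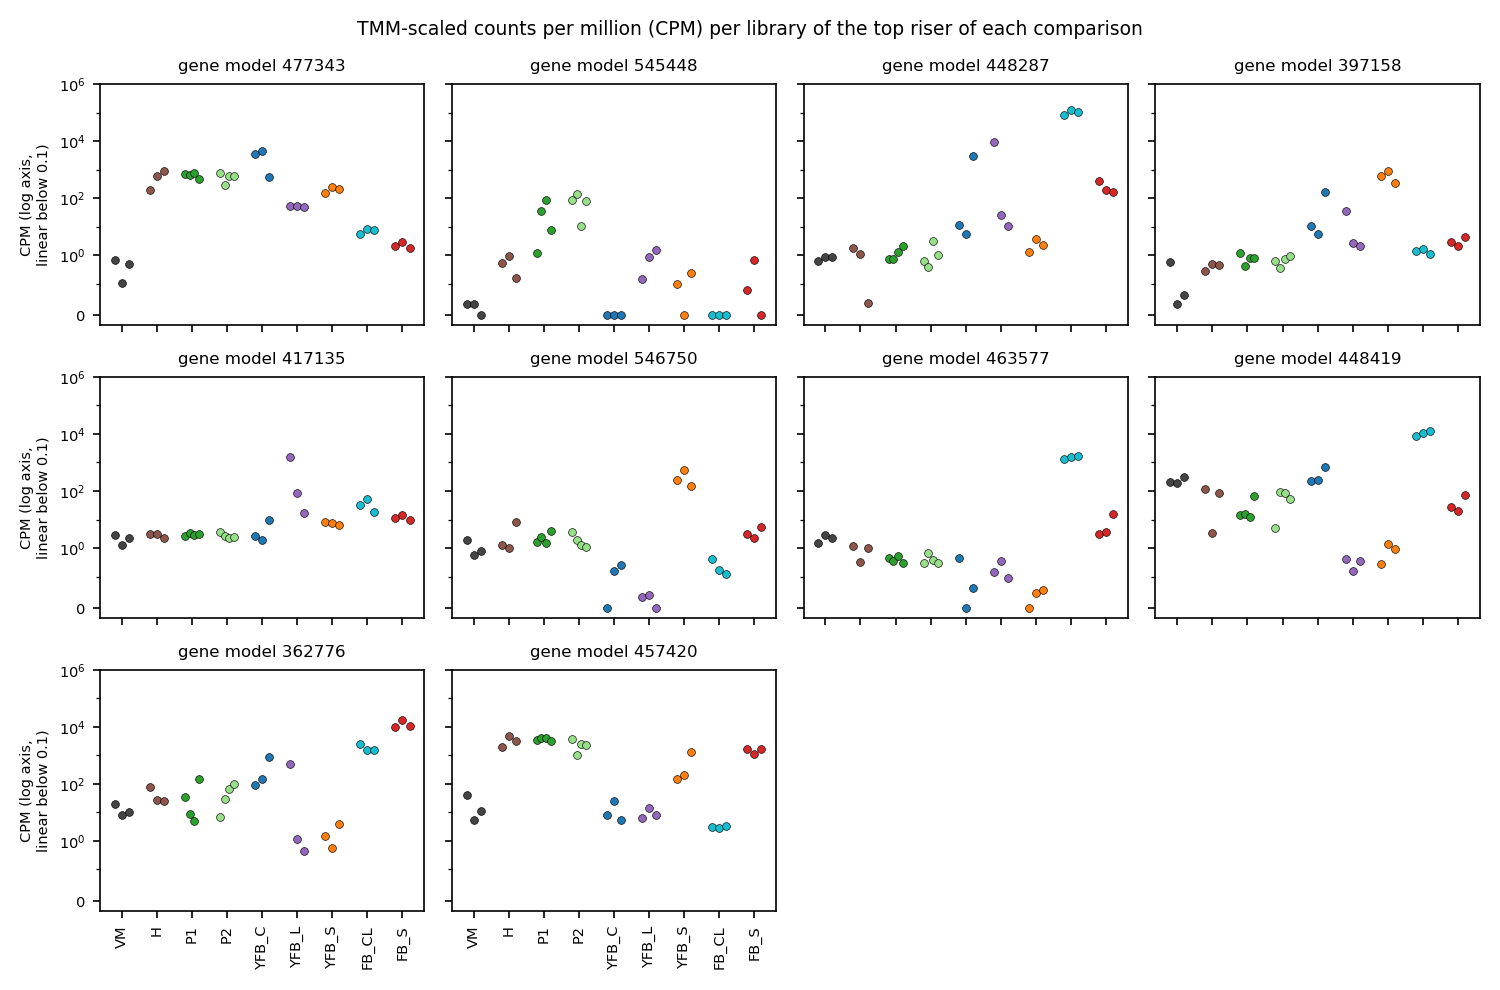
TMM-scaled CPM of 10 gene models, each the top riser of at least one comparison, on a log axis that is linear below 0.1, with one point per library by group. Among the libraries of YFB_C and YFB_L gene model 448287 is high in a single one of each, and it is highest in FB_CL, while 463577 reaches 1311 to 1704 CPM in FB_CL.

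Across the 9 groups 9033 gene models, 75.3% of those tested, differed with a range of at least 4-fold between group means (edgeR quasi-likelihood F test). Of these 1604 peaked in mycelium, 1524 in the mature cap with lamellae, 1414 in young lamellae, 1305 in the mature stipe, 1084 in the young cap and 1080 in the young stipe. Hyphal knots held 541 peaks, stage 1 primordia 323 and stage 2 primordia 158. A peak was the group with the highest fitted mean, not tested against the next group. Since edgeR called no gene model between the primordium stages, no test backs the difference of 323 and 158. All these counts of peaks also rest on the scaling. With library size alone 2887 peaked in mycelium, 2033 in young lamellae, 1219 in the young stipe, 811 in hyphal knots, 729 in the mature stipe, 691 in the young cap, 663 in stage 1 primordia, 609 in the mature cap with lamellae and 533 in stage 2 primordia.

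Genes enriched in a group, at least 4-fold above each of the other 8 groups, were most frequent in the mature cap with lamellae, with 319. They took 29.4% ± 0.542 of its reads (SD, n = 3), against a mean of at most 1.66% in another group. Young lamellae had 223 enriched genes with 8.69% ± 4.05 of the reads, mycelium 158 with 2.42% ± 0.736, and the young cap 106 with 10.4% ± 1.37 (SD, n = 3 each). The mature stipe had 99 with 8.89% ± 0.0799, the young stipe 49 with 3.11% ± 0.549 and hyphal knots 13 with 0.242% ± 0.180 (SD, n = 3 each). The 13 of hyphal knots became 7 without H replicate 3 and 32 without H replicate 4, and 31 within the first flow cell. The 223 of young lamellae became 172 without YFB_L replicate 1, which stood apart from its group, and 260 without YFB_L replicate 3. With limma on log2(RPKM + 1) and log2(RPKM + 0.1) hyphal knots had 4 and 5 and young lamellae 122 and 145, and with the stricter filter the young stipe had 32. Stage 1 and stage 2 primordia had 0 by edgeR, DESeq2 and limma, as each is compared with the other. With library size alone the mature cap with lamellae was no longer first, with 165 against 262 in young lamellae and 217 in mycelium.

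**Figure D5:**
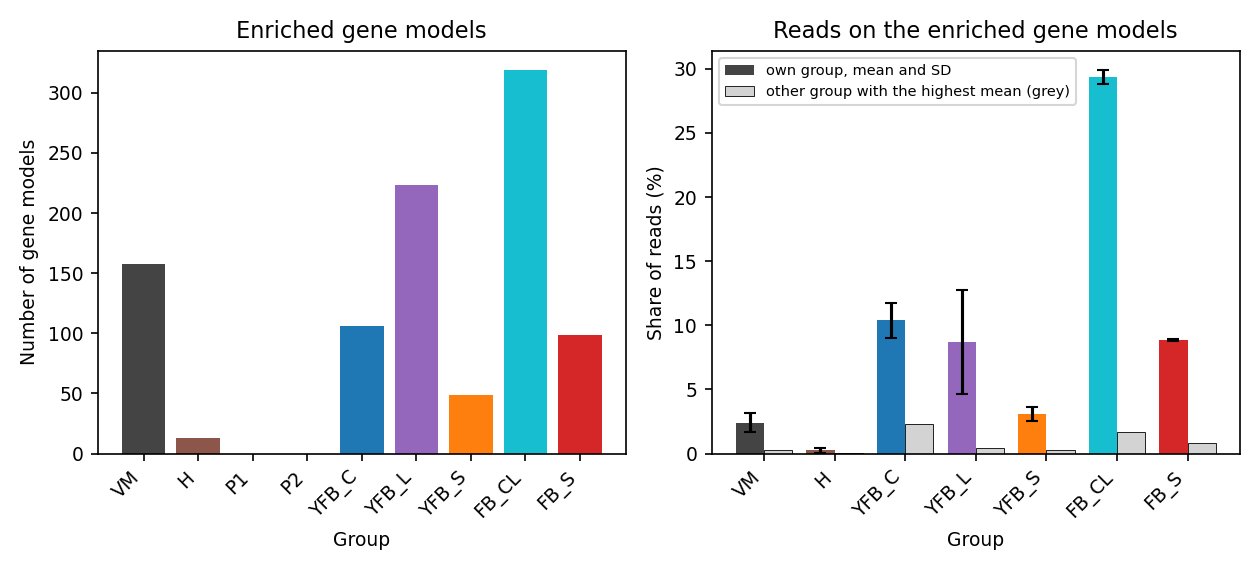
Left, number of gene models enriched at least 4-fold in each group over every other group; right, the share of reads (%) on them in their own group (coloured, mean and SD over 3 libraries) and in the other group with the highest mean (grey). The 319 gene models of FB_CL took 29.4% of its reads.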

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

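The test of stipe against cap on maturation, the test of too few libraries between the primordium stages, the tests of whether YFB_L replicate 1 and YFB_C replicate 3 lay further along or carried a swapped label and that of FB_CL RNA in the lamellae library were chosen after the data were seen.

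On maturation 2661 gene models were called in the same direction in stipe and cap, as given below, and 558 in opposite directions. The change from young to mature fruiting body differed between the stipe and the cap in 4498 gene models (edgeR interaction, at least 2-fold), 2316 with a greater change in the stipe and 2182 with a greater one in the cap, counted with sign. This split turned without YFB_C replicate 3 (2095 and 2160), without it and YFB_L replicate 1 (2319 and 2418), with limma on log2(RPKM + 1) (2138 and 2181) and at 4-fold (1350 and 1368). Of the 4498, 247 were called up in the stipe and down in the cap and 311 the reverse. The mature cap was sampled with its lamellae and the young cap without them, so part of the difference can lie between tissues. Fitted to these 12 libraries alone, the real labels gave 4412, and 2 of 100 labellings, the real one included, gave as many. The other, with 4919, kept young and mature libraries in separate groups, so that its interaction measured the stage, a structure of the samples. The next highest was 686. A first set of fewer labellings did not hold the one with 4919.

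Within the groups of 4, 3 of 24 sets of values had a library far from the rest, where chance gives about 1 in 20. In stage 1 primordia, replicate 2 had 99.8% of its reads on 1 gene model only (99.7703%, the others from 99.7769% to 99.778%). It also had 7.89 CPM of gene model 380482, where the others had 10.3 to 10.5. Replicate 4 of stage 2 primordia had 16452600 reads, where the others had 22964400 to 23501500, and it was sequenced on the second flow cell.

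Between the primordium stages edgeR and limma called 0 gene models and DESeq2 called 1 (edgeR had 212 at an unadjusted p under 0.05). With a count of 0 by edgeR, all 35 of 35 splits of the 8 libraries into groups of 4 gave as many edgeR calls by construction, which decides nothing. Too few libraries for any call is argued against, since another split called 405. That split put P2 replicate 1 with P1 replicates 1, 2 and 3, and P1 replicate 4 with the other P2 libraries. It thus differed from the stage labels only by an exchange of P2 replicate 1 and P1 replicate 4. As the highest of the other splits it was picked after the counts were seen. Whether these libraries were exchanged or staged differently was not tested and stays open. The flow cell is argued against, since 0 were called with it as a covariate or within the first flow cell. Only 1 of the 8 libraries correlated best with a library of its own stage, where chance gives about 3.4, which is consistent with stage labels that do not follow the main variation among these primordia. Whether the stages differ biologically by less than these libraries can show stays open.

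YFB_L replicate 1 and YFB_C replicate 3 stood apart from their groups. Depth is argued against, since at equal depth their correlation with their group mates stayed lower by 0.116 and 0.0624 than that of the mates with each other. An even admixture of 5% or more is argued against, since the median share of cap RNA implied by cap-enriched genes was 0.297% in the lamellae library (quartiles -1.22% and 4.36%, 10 most abundant genes -3.32% to 49.5%) and that of FB_CL RNA 0.131% in the cap library (quartiles -1.24% and 4.21%, 10 most abundant 0.352% to 20.0%), while a smaller one stays open. An even admixture of FB_CL RNA in the lamellae library is argued against. The 10 most abundant FB_CL-enriched genes stood there at a median of 0.348% of their FB_CL level, 6 of them under 1% and 448287 highest at 17.98%. Over all 374 such genes the implied share had a median of 0.199%, but its quartiles were -4.03% and 13.6%. In the cap library the median level of the 10 most abundant was 9.65%, with 1 of 10 under 1%. Across genes, the departure from one group mate correlated with the difference of FB_CL from the other at 0.42 for the lamellae and 0.30 for the cap, so that a later state may be a source, but for the lamellae the correlation was positive toward every group, 0.39 toward the young cap, and for the cap it was 0.31 toward the mature stipe. A label swapped with another of the 9 groups is argued against, since the highest correlation with a library of another group was 0.804 and 0.837, below those with the group mates (at least 0.867 and 0.926) and below the lowest within the other 7 groups (0.924). A sample from outside these groups, or one collected differently, was not tested and stays open.

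The scaling factors of mycelium and mature cap with lamellae differed 3.07-fold. If a few genes taking most of the counts were the cause, the ratio would fall toward 1 without them. Without the 100 most abundant gene models it was 2.22, which argues against these 100 as the whole source, although they may be a part. The 100 most abundant of each library took 18.7% of the reads in mycelium and 44.3% in the mature cap with lamellae. A difference in total RNA per cell was not measured, and no biological explanation was tested.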

How the results depend on the processing

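Of the alternatives, leaving out YFB_C replicate 3 and YFB_L replicate 1 together, and all those for the stipe against cap test, were chosen after the data were seen. No named gene model changed direction under the alternatives run. Which direction most called genes took did turn with library size alone, for H against VM (1067 higher and 1206 lower), YFB_C and YFB_L against P2, YFB_S against YFB_C and FB_S against FB_CL. It also turned for YFB_C and YFB_L against P2, YFB_S and FB_CL against YFB_L, and FB_CL against YFB_C without YFB_C replicate 3 and YFB_L replicate 1, and for YFB_L against YFB_C without the latter alone (2734 higher and 2935 lower). Under limma, the 4-fold threshold, a fit to only the groups compared or leaving out a library it turned for further comparisons, with the counts given beside them. With DESeq2, P2 against P1 gave 1. Library size alone gave 165 enriched in FB_CL, and the stricter filter 32 in YFB_S. The first flow cell alone gave 1090 for P1 against H and 31 enriched in H. With limma on log2(RPKM + 1), P1 against H gave 363 and the enriched counts were 4 in H and 122 in YFB_L, and on log2(RPKM + 0.1) they were 359, 5 and 145. A fit to only the groups compared gave 1 for P1 against H and 3479 for YFB_L against YFB_C. With both libraries left out P1 against H gave 1022. Neither library belongs to P1 or H, so their effect came through the filter, scaling or spread shared over all groups. Which of these it was was not tested. Elsewhere, fewer libraries or another threshold was the setting changed where used, and no cause of a moved count was tested.

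At 4-fold in place of 2-fold the counts were 1056 for H against VM, 298 for P1 against H, and 2210, 2076 and 1879 for YFB_C, YFB_L and YFB_S against P2. Between tissues they were 2758 for YFB_L against YFB_C, 1710 for YFB_S against YFB_C, 2432 for YFB_S against YFB_L and 2281 for FB_S against FB_CL. On maturation they were 2925 for FB_CL against YFB_C, 3641 for FB_CL against YFB_L, 2832 for FB_S against YFB_S and 2718 for stipe against cap. At 2-fold in place of 4-fold the enriched counts were 356 in VM, 36 in H, 291 in YFB_C, 457 in YFB_L, 235 in YFB_S, 641 in FB_CL and 384 in FB_S.

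Leaving out each library in turn gave 232 to 1008 for P1 against H and 7 to 32 enriched in H, and other counts stayed within 1.5 times. H against VM ran from 1638 to 2550. Relative log expression, no filter and the flow cell as a covariate moved no count by over 1.5 times. By the replicate numbers, no comparison had every pair correlate above 0.1 in its departures from the group means. Single pairs ran from -0.466 to 0.468, and 1 low pair is enough to fail this rule. A pairing by replicate number was thus not shown and stays open. With the number as a replicate block P1 against H gave 434, and no count moved by over 1.5 times. Over the named gene models, 913 of 921 pairs of a model and an alternative kept the call and 8 lost it, with 3 more given no adjusted p by DESeq2. Tests of gene lists were not run, since nothing paired identifiers with names. Depth limits the lowest gene models, of which 2252 were not tested.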

Other observations

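The test of gene length was planned before its result was seen, and the counts of genes shared by stipe and cap and of genes with no reads in mycelium were chosen after the data were seen.

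The group with the next highest level was recorded for the genes enriched in each group, without a test against chance. Of the 158 of mycelium, 108 (68.4%) were next highest in hyphal knots. In the other groups no next group held most of the genes. Of the 13 of hyphal knots 4 were next highest in mycelium and 4 in stage 2 primordia. Of the 223 of young lamellae 66 were next highest in the young cap and 51 in the mature cap with lamellae, and of the 106 of the young cap 28 in the mature cap with lamellae and 21 in young lamellae. Of the 49 of the young stipe 16 were next highest in the young cap and 9 in the mature stipe. Of the 319 of the mature cap with lamellae 90 were next highest in the mature stipe and 81 in young lamellae, and of the 99 of the mature stipe 35 in the mature cap with lamellae and 23 in the young cap. Among 11990 gene models, 34 had 0 reads in the 3 mycelium libraries. Of these 9 reached at least 10 CPM in another group, 5 of them highest in the mature cap with lamellae, 3 in young lamellae and 1 in stage 1 primordia.

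Many gene models changed alike in both parts on maturation, 1228 up in stipe and cap and 1433 down in both, 2661 in all. Independent lists of these sizes would share 640 and 705. The comparisons share no library.

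A hypothesis was that the called genes follow a bias of gene length. Genes that rose in the stipe on maturation differed in median length from those that fell by 14.5 bases (permutation p = 0.7, two-sided), by 0 in the more abundant and by -38 in the less abundant part of the genes. In the cap the median difference was -83.5 bases (permutation p = 0.002, two-sided), -177 and -65.5 in the 2 parts. Neither outcome fixed in advance was met, one sign in both tissues and all parts under such a bias or opposite signs in the 2 parts of a tissue without it, so a length bias stays open in both tissues.

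Other splits of the libraries were tried for each count. With 3 libraries against 3, 10 splits cannot give a share under 0.05. The real labels gave 1796 for H against VM, 3479 for YFB_L against YFB_C, 2973 for YFB_S against YFB_C, 3889 for YFB_S against YFB_L, 5281 for FB_CL against YFB_C, 5662 for FB_CL against YFB_L, 5569 for FB_S against YFB_S and 4821 for FB_S against FB_CL, each fitted to its 6 libraries alone, and the highest other was 0 in each. With 3 against 4, the real split was 1 of 35 to give as many. It gave 4800 for YFB_C, 3535 for YFB_L and 4703 for YFB_S against P2, where the highest other was 0, 0 and 2. Every other split mixes libraries of both groups, which widens the spread and lowers the calls. A share of 1 of 35 in each, not corrected over the comparisons, makes chance less likely but does not exclude it. For P1 against H it gave 1, the others 0, and a count of 1 says little. The 40 labellings of the 29 libraries included the real one. Only that one gave as many as 9033 over all groups, with 1455 as the highest other. Enriched counts were matched only by the real labelling, 1 of 40, in VM, H, YFB_C, YFB_L, YFB_S, FB_CL and FB_S, with at most 1 in another. In P1 and P2, with a count of 0, all 40 of 40 matched by construction, which decides nothing.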
